A study of Sus scrofa with 12 samples.

How the data were processed

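RNA from the ileal mucosa of 12 pigs aged 140 days was measured on 1-colour Affymetrix arrays made for the pig, whose probe sets carry the name Snowball. Per the labels' protocols, total RNA was isolated with Qiazol, treated with DNase and column-purified, then transcribed with the Ambion WT Expression Kit, fragmented and labelled with biotin. GCOS 1.1.1 is named by the submitters' processing notes. The background correction, the summary of probes into probe sets and the normalization method are not given in the sources used here. The deposited table holds log2 values for 47845 probe sets on 12 arrays. That the scale is log2 was read from the values, which run up to 14.24 with no negative value. The 12 columns have nearly the same distribution and most share the same highest value, as values normalized between arrays do, so none was added. No scan date or slide is given for these arrays, so such a batch was not tested.

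Of the 47845 probe sets, 123 are controls and were left out of the tests. Probe sets were named through the platform's gene annotation, which gives 1 gene symbol to 26426 of them, several symbols to 0 and none to 21419. Symbols were set against the gene table of the pig assembly Sscrofa11.1, used for names alone: 25851 probe sets carried a current symbol, 446 were renamed through a synonym and 129 kept a symbol that matched no entry. The 30% of probe sets with the lowest mean over all 12 arrays were left out, those under a mean log2 value of 2.67. This left 33405 probe sets, 32557 of genes and 848 of microRNAs, and the microRNA probe sets stayed in the tests. For work on genes, each of 12161 genes was represented by its probe set with the highest mean. Of the 46 gene lists fixed, 45 had at least 5 measured genes and were tested. The other list holds XIST and Y-linked genes and served to check the sex labels.

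Groups, sex and age came from the labels, with 6 pigs of high and 6 of low feed efficiency and 3 males and 3 females in each. Each array belongs to a pig with its own identifier, so the replicates are separate animals. A linear model was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with terms for feed efficiency and sex. High minus low and male minus female were taken from this fit. The difference of the feed efficiency difference between the sexes came from a fit of the 4 group means. P-values were adjusted by the Benjamini-Hochberg method over all probe sets kept, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and limma's fry beside it, adjusted over the 45 lists. A list score per pig is the mean over the list's genes of the log2 value minus its mean over the 12 arrays. Scores, components and array measures were compared by two-sided exact permutation tests. Feed efficiency labels were permuted within sex and sex labels within group, over all 400 arrangements, and 0.005 is the smallest p these can give.

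The genes named in the text followed a rule. In the feed efficiency comparison it takes the 10 genes per direction with the largest log2 difference among those past the threshold, filled up with the genes of smallest unadjusted p. The sex comparison and the difference between the sexes take 5 genes per direction. Genes without a proper symbol were not used to fill. To these it adds up to 4 members of each list described, by smallest p (the text gives up to 2), and every measured gene of the ileal bile acid list and of the list that checks the sex labels. The groups, tests, covariates, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other filters on dim probe sets, quantile normalization or median centring, a trended and robust variance, array weights and looser thresholds. Further terms in the model were also tried, or its terms left out (a residual component, the score of B cells or of smooth muscle, the range of pig identifiers), as were males, females or 1 identifier range alone, and each pig left out in turn. For the lists, they were other correlations, ranks, fry and the mean over a gene's probe sets. Leaving out 2 arrays together and testing 1 probe set per gene were added after the data were seen.

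The pipeline was tested on simulated data with the real number of probe sets, 33405, of which 100 were changed by 1 and 100 by 2 on the log2 scale in each comparison. For feed efficiency 61% of the former and 96% of the latter were called, and 9 unchanged probe sets were called. For sex the shares were 58% and 92%, with 9 unchanged probe sets called. For the difference between the sexes they were 4% and 50%, with 3. Of 45 lists run, the 3 shifted by a log2 of 0.5 were all called and none of the other 42 was. The simulated genes varied independently, so this could not show false calls that arise when a list's genes vary together. In the real data the estimated correlation within a list reached 0.74 (B cells). Random splits of the real pigs within sex called a median of 12 lists for feed efficiency. The number of arrays limits the precision. The median 95% confidence interval of a probe set reached 0.37 to either side of its log2 difference for feed efficiency and sex, and 0.76 for the difference between the sexes. The median level of the array's own background probe sets lay between 2.43 and 2.71, so values near or below that carry little signal. Figures were drawn with matplotlib 3.10.9.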

Results

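Feed efficiency describes how well an animal turns feed into growth, and the ileum, the last part of the small intestine, takes up bile acids and much of what is left of the digested feed. The series profiled transcripts in the ileal mucosa of 12 pigs at 140 days of age, 6 of high and 6 of low feed efficiency, with 3 males and 3 females in each group. Pig identifiers fall into 2 ranges, 301 to 310 with 8 pigs and 317 to 324 with 4 pigs. Both ranges hold both feed efficiency groups, but the second holds no male and the first holds 2 females, so sex and range overlap in part. Pairwise correlations between arrays over the probe sets kept ran from 0.852 to 0.973, with a median of 0.948. At most 0.323% of values were identical between a pair of arrays, so no array is a copy of another.

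Arrays of both groups had similar medians (4.25 ± 0.04 in high and 4.23 ± 0.04 in low feed efficiency, SD, n = 6 each, exact permutation p = 0.29). The array of high feed efficiency pig 1 stood apart, with a median correlation with the others of 0.899 and hybridization controls at 11.02, against 10.26 to 10.62 on the other arrays. On the first principal component, which held 30.5% of the variance, this pig lay at -107.7 and low feed efficiency pig 2 came next at -44.8. Feed efficiency groups did not separate on that component (exact permutation p = 0.29). The male minus female difference on it was -56.8 (exact permutation p = 0.015, adjusted over 6 tests 0.09). Components 2 and 3 held 17.9% and 9.98% of the variance, with exact permutation p of 0.945 and 0.705 for feed efficiency and 0.27 and 0.45 for sex.

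**Figure D1:**
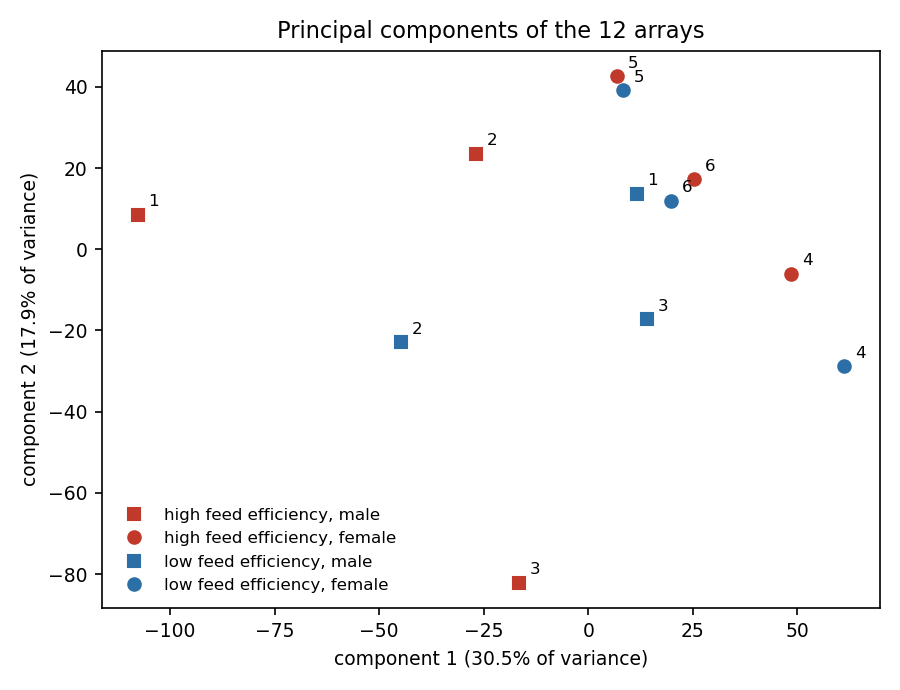
First and second principal components of the 12 arrays (horizontal and vertical axis, in component units), coloured by feed efficiency, with squares for males, circles for females and the replicate number beside each point. High feed efficiency pig 1 lies at -107.7 on the first component, and the feed efficiency groups overlap on both.

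The main question of the series is which ileal transcripts differ between pigs of high and low feed efficiency. Among the genes of smallest p, RAB11FIP5 and ATP10B differed most, both with lower values in high feed efficiency. RAB11FIP5, which acts in vesicle recycling, differed by -1.35 ± 0.41 on the log2 scale (SE, n = 6 per group), and ATP10B, a phospholipid flippase, by -1.06 ± 0.26. The terminal complement component C9 differed by -0.88 ± 0.26, and PPGRP-S, a peptidoglycan recognition protein, by -0.77 ± 0.21. Higher in high feed efficiency were ICA1L (0.98 ± 0.32) and XG, a blood group antigen gene (0.59 ± 0.13). None of these passed the threshold after adjustment (limma adjusted p of at least 0.999 for each). RAB11FIP5 lay near background, so its size is not measured exactly, and the other of its 2 probe sets had the opposite sign. For ICA1L, low feed efficiency pig 6 read 1.73, below background, with the next pig of its group at 2.87. The ICA1L difference was 0.43 in males and 1.52 in females, so its size is not measured exactly either.

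With limma, 0 of 33405 probe sets passed an adjusted p of 0.05, and 0 passed at 0.1 or 0.2. An unadjusted p under 0.05 was reached by 1059 probe sets (584 higher and 475 lower in high feed efficiency), 3.17% of those tested. On the level of genes, 0 of 12161 passed and 306 had an unadjusted p under 0.05. The median absolute log2 difference was 0.12, with a median SE of 0.17.

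**Figure D2:**
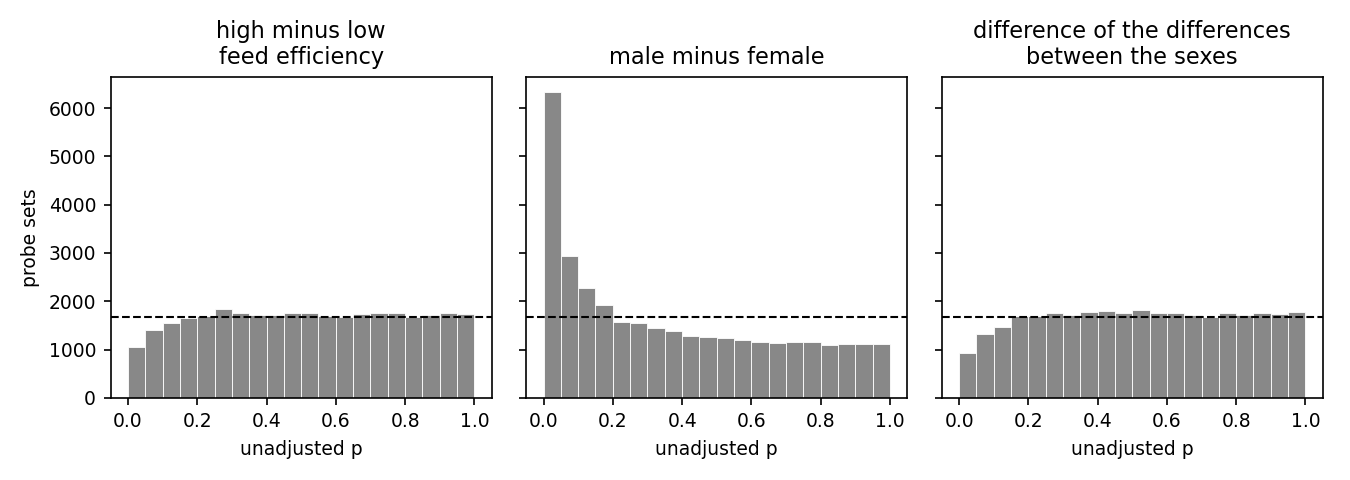
Number of probe sets (vertical axis) per bin of unadjusted p (horizontal axis) for the comparison of feed efficiency, of sex, and of the feed efficiency difference between the sexes. The dashed line marks the 1670 probe sets per bin of an even spread, and the first bin holds 1059, 6332 and 922 probe sets.

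The other genes of smallest p were spread over many functions. Among those higher in high feed efficiency were the RNA-binding proteins RBM23 (0.47 ± 0.13) and CELF1 (0.51 ± 0.16), MSRB2, a mitochondrial enzyme that repairs oxidized methionine (0.47 ± 0.14), and RHOT2, a GTPase of mitochondrial transport (0.50 ± 0.16). GZMM, a granzyme of cytotoxic lymphocytes, differed by 0.35 ± 0.11, TXLNG by 0.46 ± 0.14, MPP3 by 0.51 ± 0.16 and SPATA5 by 0.38 ± 0.11. On the lower side stood TNFSF10, the death ligand TRAIL (-0.60 ± 0.15), TTLL9 (-0.64 ± 0.14), ZNF181 (-0.52 ± 0.14) and LXN, a carboxypeptidase inhibitor (-0.49 ± 0.14). ANKRD33 differed by -0.43 ± 0.11 and ING2 by -0.43 ± 0.12. For XG and MSRB2 the values of the 6 high and 6 low pigs did not overlap. Both were picked by small p in this same comparison, which favours such a split. How many of the 33405 probe sets split in this way was not counted, so it adds no support. RBM23 and GZMM each had 2 probe sets, and the other one had the opposite sign. The fit of females alone called 1 probe set, of CYP4A24, described under the difference between the sexes.

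**Figure D3:**
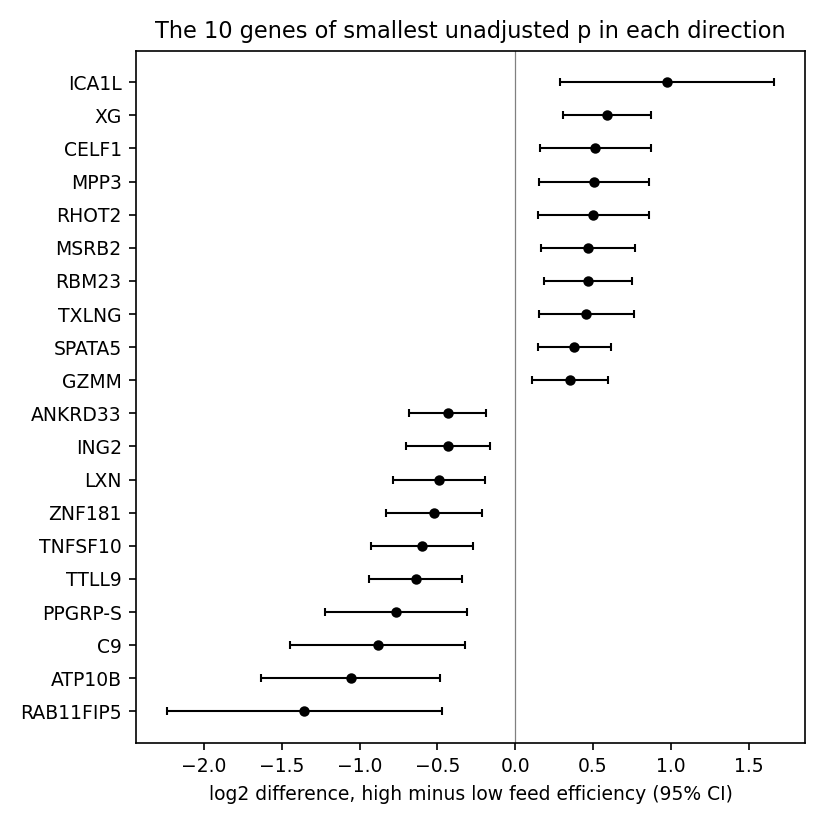
Log2 difference, high minus low feed efficiency (horizontal axis), of the 10 genes per direction with the smallest unadjusted p (vertical axis), with 95% confidence intervals, n = 6 per group. Differences run from -1.35 for RAB11FIP5 to 0.98 for ICA1L, and none passed the adjusted threshold.

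Several lists of uptake and metabolism were lower in high feed efficiency by camera, although no single member of any of the 45 lists passed, also when adjusted over the list alone (0 genes). Others were not called: sugar transport (camera adjusted p = 0.556), amino acid and peptide transport (0.765), glycolysis and glucose metabolism (0.482), fatty acid synthesis (0.577) and cholesterol biosynthesis (0.943). Brush border enzymes and structure genes were lower in 16 of 18 measured members, with a mean log2 difference of -0.39 (camera adjusted p = 0.00118, 0.626 with an estimated correlation), for example the aminopeptidase ANPEP (-0.49 ± 0.32) and ESPN (-0.30 ± 0.16). Genes of lipid absorption and chylomicron assembly were lower in 21 of 23 (mean -0.34, camera adjusted p = 0.00409, 0.626 with an estimated correlation), with the apolipoproteins APOA4 (-0.98 ± 0.37) and APOC3 (-0.55 ± 0.31). Of the 3 probe sets of APOA4, 2 had the sign given. Mineral, vitamin and ion transport was lower in 21 of 29 members (mean -0.21, camera adjusted p = 0.0232, 0.626 with an estimated correlation), including the zinc exporter SLC30A1 (-0.47 ± 0.20) and ferritin heavy chain FTH1 (-0.25 ± 0.11).

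Fatty acid oxidation and ketogenesis was lower in 22 of 25 members (mean -0.15, camera adjusted p = 0.0149, 0.626 with an estimated correlation), with CPT1A, which carries fatty acids into mitochondria, at -0.45 ± 0.23 and BDH1 at -0.26 ± 0.15. Amino acid catabolism and the urea cycle was lower in 19 of 23 (mean -0.19, camera adjusted p = 0.0232, 0.626 with an estimated correlation), with ARG2 at -0.36 ± 0.14 and NAGS at -0.47 ± 0.25. Xenobiotic and steroid metabolism was lower in 16 of 21 (mean -0.19, camera adjusted p = 0.0392, 0.626 with an estimated correlation), with CYP2C33 at -0.63 ± 0.36 and TIPARP at -0.17 ± 0.11. Oxidative phosphorylation was lower in 31 of 34 members (mean -0.10, camera adjusted p = 0.0251, 0.827 with an estimated correlation) and tight and adherens junctions in 21 of 28 (mean -0.20, camera adjusted p = 0.015, 0.813 with an estimated correlation). ATP5G1 stood at -0.27 ± 0.17, PKP2 at -0.41 ± 0.21 and CLDN7 at -0.56 ± 0.34, while NDUFA4 of the respiratory chain stood at 0.27 ± 0.14. NDUFA4 (mean 2.81 in low feed efficiency) and CYP2C33 (mean 2.825 in high feed efficiency) lay near background. CPT1A and CLDN7 each had 2 probe sets, and the other one had the opposite sign.

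Without high feed efficiency pig 1, camera called 9 lists in place of 18, and 8 of the 18 were among them. The brush border list then had an adjusted p of 0.366 and lipid absorption 0.209. The others lost were fatty acid oxidation (0.366), amino acid catabolism (0.209), mineral transport (0.38), tight junctions (0.417), xenobiotic metabolism (0.454), oxidative phosphorylation (0.899), immediate early genes (0.129) and B cells (0.314). Without that pig the difference of the brush border score was -0.06 in place of -0.39. In the scores with the pig as the unit, brush border was -0.20 ± 0.89 in high and 0.20 ± 0.28 in low feed efficiency (SD, n = 6 each, exact permutation p = 0.395).

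Lists of defence genes were also called. Of 33 measured type I interferon response genes 32 were lower (mean -0.27, camera adjusted p = 6.6e-05, 0.626 with an estimated correlation), among them DTX3L (-0.55 ± 0.22) and the antiviral effector IFIT3 (-0.58 ± 0.29). Of 26 genes of the interferon gamma response and of antigen processing for MHC class I, 22 were lower (mean -0.23, camera adjusted p = 0.00118, 0.626 with an estimated correlation), with the guanylate-binding proteins GBP1 (-0.44 ± 0.22) and GBP2 (-0.63 ± 0.32). The type I list was no longer called without low feed efficiency pig 4 (adjusted p = 0.0593), whose score was 0.978. Antimicrobial defence of the epithelium was lower in 22 of 29 members (mean -0.22, camera adjusted p = 0.00391, 0.419 with an estimated correlation), including the lectin REG4 (-0.58 ± 0.24) besides PPGRP-S. Complement and coagulation was lower in 18 of 24 (mean -0.18, camera adjusted p = 0.0392, 0.626 with an estimated correlation), with C6 at -0.69 ± 0.28 and C5 at -0.81 ± 0.37. Per pig, the antimicrobial score came closest to a difference (-0.11 ± 0.31 against 0.11 ± 0.17, exact permutation p = 0.065), and the type I interferon score gave an exact permutation p of 0.30. Adjusted over the 45 lists, the lowest p of any score was 0.85.

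Lists of cell types and stress responses were also called by camera at the preset correlation. Plasma cell genes were lower in 13 of 17 members (mean -0.14, camera adjusted p = 0.0116, 0.626 with an estimated correlation), with TXNDC5 at -0.39 ± 0.17 and PIM2 at -0.39 ± 0.20. This list shares members with that of the unfolded protein response, among them PDIA4 and XBP1, so the 2 calls are not independent. The unfolded protein response was lower in 18 of 20 (mean -0.11, camera adjusted p = 0.00957, 0.626 with an estimated correlation), with DNAJB9 at -0.30 ± 0.10 and DNAJC3 at -0.35 ± 0.17, and immediate early genes in 16 of 24 (mean -0.12, camera adjusted p = 0.0318, 0.626 with an estimated correlation), with JUNB at -0.38 ± 0.15 and JUND at -0.28 ± 0.13. Higher in high feed efficiency were smooth muscle (22 of 29 members, mean 0.13, camera adjusted p = 0.015, 0.813 with an estimated correlation), with NEXN at 0.47 ± 0.21 and MYH11 at 0.35 ± 0.20, and enteric neurons and glia (13 of 18, mean 0.09, camera adjusted p = 0.026, 0.419 with an estimated correlation), with PRPH at 0.34 ± 0.12 and HAND2 at 0.31 ± 0.16. B cells and germinal centres were higher in 18 of 22 members (mean 0.26, camera adjusted p = 0.0326, 0.852 with an estimated correlation), with EBF1 at 0.41 ± 0.33 and BCL6 at 0.35 ± 0.35. The other of the 2 probe sets of BCL6 had the opposite sign, and of the 4 probe sets of DNAJC3, 3 had the sign given. The B cell direction rested on low feed efficiency pig 4 (score -2.01): it turned without that pig (adjusted p = 0.341), and in males alone the score difference was -0.03. Without high feed efficiency pig 3 the smooth muscle (adjusted p = 0.768), enteric neuron (0.19) and plasma cell (0.23) lists were no longer called, and without low feed efficiency pig 1 those of the unfolded protein response (0.056), immediate early genes (0.226) and complement (0.274).

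Several of the list members named moved by over 1.5 times when a single pig was left out. Without high feed efficiency pig 1 the difference was -0.20 for ANPEP, -0.30 for NAGS, -0.22 for DNAJC3, -0.20 for PKP2, -0.26 for CLDN7, -0.44 for C6 and -0.46 for C5. With high feed efficiency pig 3 left out it was -0.15 for BDH1, -0.24 for PIM2, 0.17 for MYH11 and 0.20 for HAND2. Leaving out low feed efficiency pig 4 gave -0.17 for ESPN, -0.37 for APOC3 and 0.10 for BCL6, leaving out low feed efficiency pig 3 gave 0.19 for EBF1 and 0.31 for NEXN, and leaving out low feed efficiency pig 2 gave -0.29 for CYP2C33.

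Genes of ileal bile acid handling, the segment's own task, gave no call (5 of 7 members lower, mean -0.29, camera adjusted p = 0.118). The bile acid transporter SLC10A2 differed by 0.11 ± 0.50 and the bile acid binding protein FABP6 by -0.11 ± 0.21. The bile acid receptor NR1H4 stood at -0.61 ± 0.31, its target NR0B2 at -0.46 ± 0.37, the exporter ABCC2 at -0.72 ± 0.70, NR1I2 at -0.26 ± 0.29 and GATA4 at 0.01 ± 0.13. Of the 5 probe sets of NR1I2, 4 had the sign given. Leaving out high feed efficiency pig 1 gave -0.37 for NR1H4, -0.27 for NR0B2, -0.16 for ABCC2 and -0.05 for NR1I2. The signs of FABP6, SLC10A2 and GATA4 turned when single pigs were left out, and that of GATA4 also after quantile normalization. Over all 45 lists, camera called 18 (15 lower and 3 higher), 0 with an estimated correlation (2 at an unadjusted p under 0.05) and fry called 0 (2 at an unadjusted p under 0.05).

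**Figure D4:**
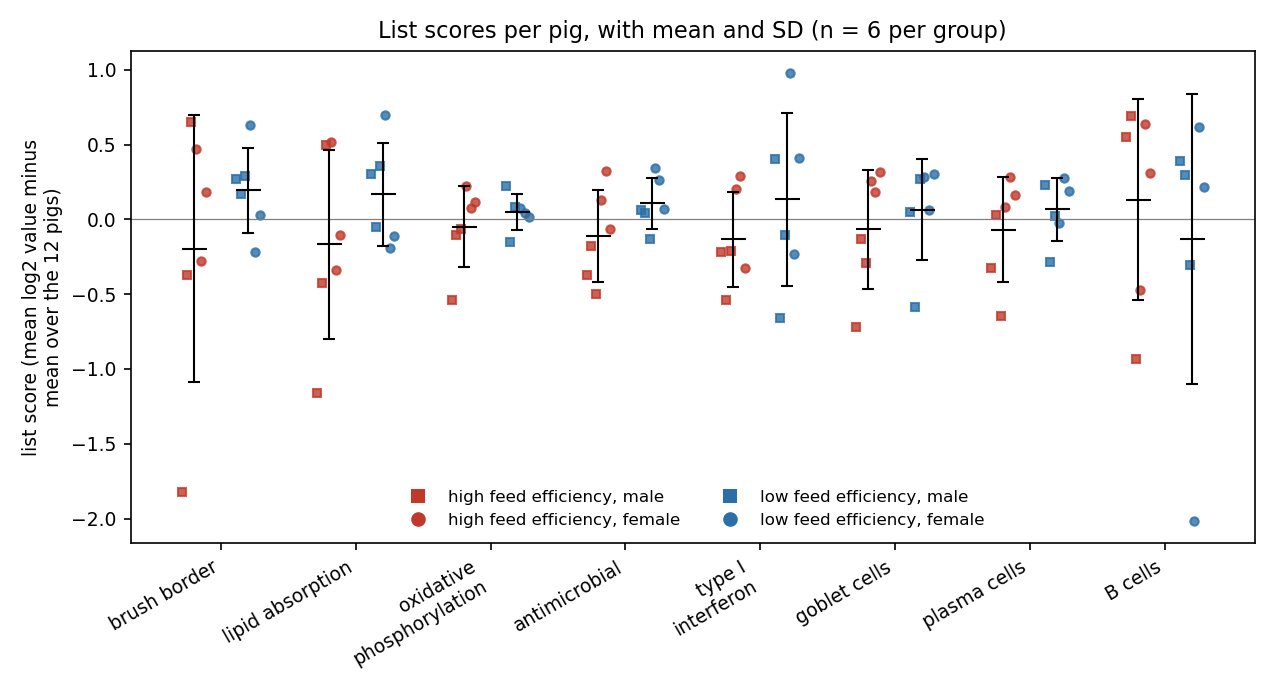
Score of 8 gene lists (horizontal axis) in each pig, as the mean log2 value of a list's genes minus their mean over the 12 pigs (vertical axis), with mean and SD of 6 pigs per group. High feed efficiency pig 1 has the lowest brush border score, -1.82, and low feed efficiency pig 4 the lowest B cell score, -2.01.

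The second comparison the design allows is that of males with females, which also checks the sex labels. Males and females were set apart by a few probe sets with very large differences and by broad, smaller shifts. The arrays themselves differed too, with a median of 4.26 ± 0.04 in males and 4.22 ± 0.01 in females (SD, n = 6 each, exact permutation p = 0.03) and a brightest 10% at 8.87 ± 0.15 and 8.99 ± 0.03 (exact permutation p = 0.055). A pair of probe sets without a gene name, 037083 and 023078, were at or below background in males (2.02 ± 0.15 and 2.21 ± 0.29, SD, n = 6) and bright in females (7.54 ± 0.07 and 6.99 ± 0.17, n = 6). A probe set of KDM6A, an X-linked histone demethylase, was higher in males by 3.09 ± 0.20 (SE). By camera, 10 lists were lower in males, among them those of plasma cells, macrophages, goblet cells and fibroblasts, and that of the cell cycle was higher, each with an adjusted p of 0.818 with an estimated correlation.

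With limma, 11 of 33405 probe sets passed (8 higher and 3 lower in males), 580 passed at 0.1 (424 higher and 156 lower), and 6332 had an unadjusted p under 0.05 (3270 higher and 3062 lower), 18.96% of those tested. With 1 probe set per gene, 0 of 12161 genes passed at 0.05 and 195 at 0.1, with 2581 at an unadjusted p under 0.05. The 11 probe sets were named after their values were seen. Besides 037083 (-5.53, limma adjusted p = 1.67e-11), 023078 (-4.78, 6.22e-09) and the KDM6A probe set SNOWBALL_023193_s_st (adjusted p = 2.76e-05), they were SNOWBALL_028804_st (-2.78), SNOWBALL_035896_st (2.72), bta-mir-562 (1.85), TMED10 (1.63), SNOWBALL_033704_st (1.36), PSPC1 (1.09), SNOWBALL_044653_st (1.03) and CEBPG (0.95). Males and females did not overlap in any of the 11, which were picked by their p in this same comparison. Except for KDM6A, PSPC1 and CEBPG, the lower sex lay at or near background (means from 1.85 to 2.59), so the sizes of those differences are not measured exactly. Within identifier range 301 to 310 (6 males, 2 females) the first 3 stood at -5.53, -4.74 and 3.21 and passed again, and the other 8 kept their sign without passing.

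The 2 measured genes of the list fixed to check the sex labels did not separate the sexes. The probe set named EIF1AY read 7.28 ± 0.33 in males and 7.60 ± 0.22 in females (exact permutation p = 0.07), and SRY lay below the filter in both (1.70 ± 0.39 and 1.67 ± 0.67, exact permutation p = 0.895). The 4 probe sets of KDM6A disagreed, each with an exact permutation p of 0.005. Males were higher on SNOWBALL_023193_s_st and, near background, on SNOWBALL_023192_st (2.98 against 1.86), and lower on SNOWBALL_020166_st (7.08 against 7.60) and SNOWBALL_023445_st (4.37 against 5.82).

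**Figure D5:**
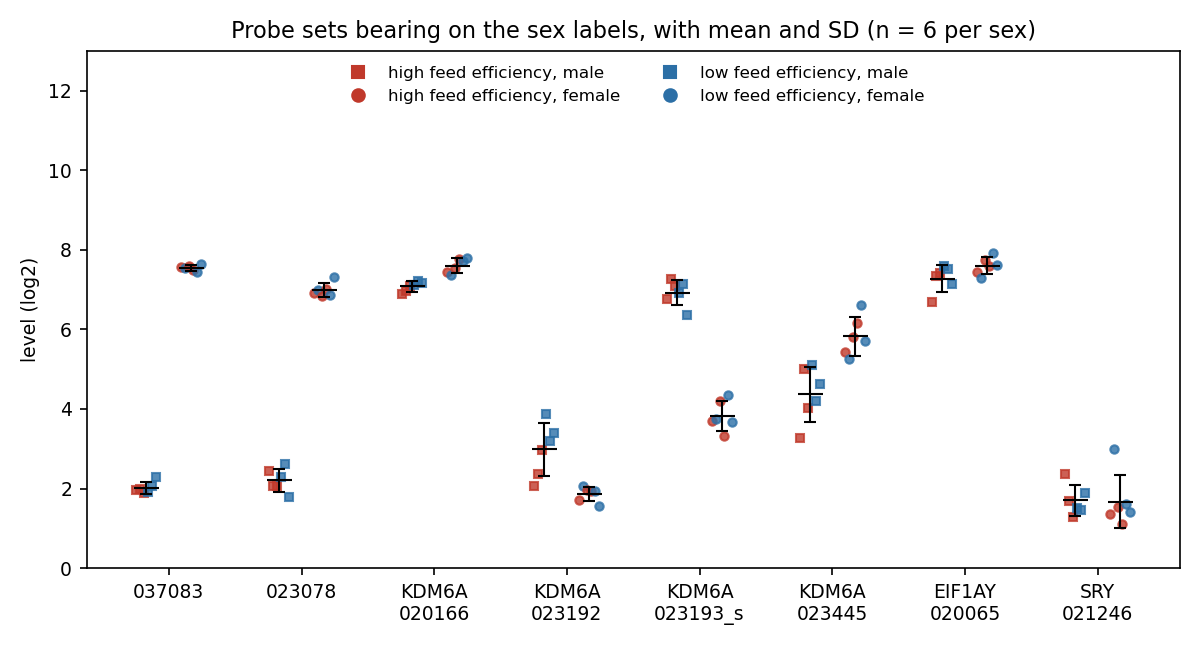
Level (log2, vertical axis) of 8 probe sets in each pig, males and females side by side, with mean and SD of 6 pigs per sex. The probe sets 037083 and 023078 and each KDM6A probe set split males from females, while those named EIF1AY and SRY do not.

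The genes taken by the naming rule had adjusted p between 0.0798 and 0.0905. Higher in males were REV3L, the catalytic part of a translesion polymerase (1.06 ± 0.18), RBM41 (1.02 ± 0.19), ALG13 of protein glycosylation (0.90 ± 0.17), the apoptosis inhibitor BIRC6 (0.81 ± 0.15) and SPATA5 (0.63 ± 0.11). Lower were S100A14 (-1.21 ± 0.23), EFHD2 (-0.85 ± 0.16), PI16 (-0.79 ± 0.16), ERF (-0.79 ± 0.16) and TMEM115 (-0.75 ± 0.13). Within range 301 to 310 they kept their sign, from 0.65 to 1.14 for the former and from -1.41 to -0.70 for the latter.

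Camera called 11 of 45 lists between the sexes, 10 lower in males and 1 higher, 0 of them with an estimated correlation (adjusted p = 0.818 for each of the 11; 0 lists at an unadjusted p under 0.05). Fry called 0 lists, with 9 at an unadjusted p under 0.05 and a lowest adjusted p of 0.132. Goblet cell and mucus genes were lower in 18 of 22 members (mean -0.47, camera adjusted p = 0.0107, 0.818 with an estimated correlation), 3 of them past the threshold adjusted over the list alone, with SPINK4 at -1.21 ± 0.34 and the trefoil factor TFF2 at -1.40 ± 0.40. The other of the 2 probe sets of SPINK4 had the opposite sign. Plasma cell genes were lower in 15 of 17 (mean -0.33, camera adjusted p = 0.0041, 0.818 with an estimated correlation), 7 of them adjusted over the list alone, among them TXNDC5 (-0.75 ± 0.17) and XBP1, which drives antibody secretion (-0.69 ± 0.16). XBP1 is also a member of the unfolded protein response list, which was not called by sex (camera adjusted p = 0.111). Markers of macrophages, monocytes and dendritic cells were lower in 26 of 33 (mean -0.37, camera adjusted p = 0.00731, 0.818 with an estimated correlation), 9 of them adjusted over the list alone, with CD209 at -1.55 ± 0.38. Complement and coagulation was lower in 20 of 24 (mean -0.32, camera adjusted p = 0.0291, 0.818 with an estimated correlation), 2 of them adjusted over the list alone, with CFP at -1.05 ± 0.23 and CFB at -1.43 ± 0.38.

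In the other 7 lists no gene passed when adjusted over the list alone. Type I interferon response genes were lower in males in 29 of 33 (mean -0.44, camera adjusted p = 0.00103, 0.818 with an estimated correlation), with IRF9 at -0.72 ± 0.20 and XAF1 at -0.93 ± 0.27, and the interferon gamma list in 21 of 26 (mean -0.25, camera adjusted p = 0.0313, 0.818 with an estimated correlation), with PSME1 at -0.56 ± 0.17 and PSMB8 at -0.86 ± 0.27. The other of the 2 probe sets of PSME1 had the opposite sign, and of the 7 probe sets of PSMB8, 5 had the sign given. Cytotoxic lymphocytes and NK cells were lower in 19 of 22 (mean -0.41, camera adjusted p = 0.0165, 0.818 with an estimated correlation), with FCER1G at -0.84 ± 0.22 and TYROBP at -1.03 ± 0.31. Both genes are also members of the list of macrophages, monocytes and dendritic cells. Fibroblasts and extracellular matrix were lower in 31 of 38 (mean -0.24, camera adjusted p = 0.0165, 0.818 with an estimated correlation), with BGN at -0.66 ± 0.18 and SFRP1 at -0.76 ± 0.25. Glycolysis and glucose metabolism was lower in 17 of 20 (mean -0.34, camera adjusted p = 0.0165, 0.818 with an estimated correlation), with the gluconeogenic enzymes G6PC (-1.62 ± 0.51) and PCK1 (-1.32 ± 0.44), and immediate early genes in 21 of 24 (mean -0.20, camera adjusted p = 0.0475, 0.818 with an estimated correlation), with GADD45B at -0.58 ± 0.18. Within range 301 to 310, G6PC stood at -0.93 and PCK1 at -1.23. Of the 3 probe sets of PCK1, 2 were lower in males over all pigs. Cell cycle genes were higher in 43 of 54 (mean 0.20, camera adjusted p = 0.00403, 0.818 with an estimated correlation), with the centromere protein CENPE at 1.17 ± 0.29 and POLA1 at 0.60 ± 0.17. The B cell score lay beside that of the cell cycle, at 0.12 in males and -0.12 in females (exact permutation p = 0.695), and its list was not called (camera adjusted p = 0.162). Within range 301 to 310 the B cell difference was 1.36, from 6 males and 2 females, 1 of them low feed efficiency pig 4. Without low feed efficiency pig 4, with the lowest B cell score, the lists of the cell cycle (adjusted p = 0.12), interferon gamma (0.117) and complement (0.0603) were no longer called. The same held for cytotoxic lymphocytes (0.0962), fibroblasts (0.118) and immediate early genes (0.0962) without low feed efficiency pig 2, and for glycolysis (0.0512) without high feed efficiency pig 1, which also ended the calls of fibroblasts (0.0621) and immediate early genes (0.0783). With both of these pigs left out, the goblet cell list was lost as well (adjusted p = 0.0514), and their goblet cell scores were -0.719 (high) and -0.583 (low). Bile acid genes differed by -0.63 (SLC10A2) to -0.01 (NR0B2), with signs that turned without single pigs for FABP6, NR1I2, ABCC2, GATA4 and NR0B2, and their list was not called (camera adjusted p = 0.423). Within range 301 to 310 they ran from -1.69 (ABCC2, -0.37 over all pigs) to -0.20 (GATA4). NR1H4 stood at -0.25 there and at -0.61 over all pigs. Of the 5 probe sets of NR1I2, 2 were lower in males over all pigs.

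Per pig, the goblet cell score was -0.23 ± 0.38 in males and 0.23 ± 0.10 in females (SD, n = 6 each, exact permutation p = 0.01), and the antimicrobial score -0.18 ± 0.22 and 0.18 ± 0.16 (exact permutation p = 0.005, the smallest possible). The antimicrobial list was not called by camera (adjusted p = 0.0812). Of the lists that were, the cell cycle score gave an exact permutation p of 0.46, fibroblasts 0.14 and type I interferon 0.115. Interferon gamma gave 0.095 and cytotoxic lymphocytes 0.08. The scores of plasma cells, macrophages, goblet cells, glycolysis, complement and immediate early genes were under 0.05 before adjustment. In all, 11 of 45 scores had an exact permutation p under 0.05, and the lowest adjusted p was 0.15. Within range 301 to 310 the male minus female score was -0.50 for goblet cells, -0.20 for plasma cells, -0.23 for macrophages, -0.35 for complement, -0.81 for type I interferon and 0.71 for the cell cycle. With the range as a term, the plasma cell and macrophage lists were no longer called (adjusted p = 0.0705 and 0.198), and the other 9 were. The second range holds no male, so both checks compare the 6 males with the 2 females of range 301 to 310. Low feed efficiency pig 4 is 1 of these females, with scores of 0.978 for type I interferon and -0.729 for the cell cycle. The size of a sex difference went with brightness, from a median log2 of 0.03 among the dimmest 3341 probe sets to -0.13 among the brightest 3341. The median went from 0.02 to -0.05 for feed efficiency and from 0.05 to -0.15 for the difference between the sexes.

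A last comparison asks whether the feed efficiency difference is the same in males and females. GKN3, a gastrokine, differed by 3.08 between high and low feed efficiency males and by -2.14 in females, a difference of 5.22 ± 0.91. PDE2A, a cyclic nucleotide phosphodiesterase, went the other way (-3.57 ± 0.95), as did BTN1A1 (-2.14 ± 0.52). The lowest values of GKN3 (2.05) and PDE2A (1.66) lie below background, so the sizes for these genes are not measured exactly. A probe set of CYP4A24, a fatty acid hydroxylase of the CYP4A family, singled out after its values were seen, was near or below background in the 3 high feed efficiency females (1.28 ± 0.18) and at 4.35 ± 0.22 in the 3 low ones, against 4.80 ± 1.15 and 3.77 ± 0.71 in males. It was the probe set called in females alone (limma adjusted p = 0.022), with a size that is not measured since the high females lie below background, while its difference between the sexes had an adjusted p of 0.699 over all pigs and of 0.0364 without high feed efficiency pig 3.

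None of these differences passed. With limma, 0 of 33405 probe sets passed at 0.05 and 2 at 0.2 (lowest adjusted p = 0.176), with 922 at an unadjusted p under 0.05 (520 above and 402 below 0). The other genes of the naming rule were KCNMB3 (1.52 ± 0.44), CTNNA3 (1.40 ± 0.41, near background), DOCK4 (1.20 ± 0.35) and OTUD6B (1.07 ± 0.31) on the positive side. On the negative side they were TMEM106C (-1.09 ± 0.30), PCCB of propionate breakdown (-0.995 ± 0.284) and RPL22L1 (-0.93 ± 0.29). The lowest adjusted p among these genes was 0.699, for GKN3.

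Camera called 4 of 45 lists, each with a lower feed efficiency difference in males than in females, and 0 with an estimated correlation (adjusted p = 0.945 for each). Oxidative phosphorylation was on the negative side in 31 of 34 members (mean -0.38, camera adjusted p = 1.87e-08, 0.945 with an estimated correlation), with NDUFS4 at -0.59 ± 0.20 and ATP5A1 at -0.49 ± 0.22, and cytosolic ribosomal proteins in 48 of 55 (mean -0.31, camera adjusted p = 7.04e-06, 0.945 with an estimated correlation), with RPLP1 at -0.70 ± 0.25 and RPL18 at -1.15 ± 0.47 (-0.71 without high feed efficiency pig 1). Brush border genes (mean -0.74) and plasma cell genes (mean -0.33) had a camera adjusted p of 0.0441 each, and 0.945 with an estimated correlation, with 16 of 18 and 12 of 17 members on that side. GGT1 stood at -1.48 ± 0.70 and TREH at 0.78 ± 0.30 in the former, TNFRSF17 at -1.27 ± 0.49 and XBP1 at -0.67 ± 0.28 in the latter. With an estimated correlation 0 lists had an unadjusted p under 0.05, fry called 0 (0 at an unadjusted p under 0.05), and no gene passed when adjusted over the list alone. Without high feed efficiency pig 1 the brush border list had an adjusted p of 0.963, while that of oxidative phosphorylation was 3.95e-05. Ribosomal proteins (adjusted p = 0.0911) and plasma cells (0.372) were no longer called without high feed efficiency pig 3, and of the 4 lists the oxidative phosphorylation list alone stayed called without each single pig. Bile acid genes ran from -1.29 (ABCC2) to 0.42 (GATA4), with -0.20 for ABCC2 without high feed efficiency pig 1 and signs that turned without single pigs for NR1H4, NR1I2 and SLC10A2, and were not called as a list (camera adjusted p = 0.615).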

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

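The counts from random splits of all 12 pigs were planned before the result was seen, and the other tests weighed here, among them the splits of 10 and of 8 pigs, were chosen only afterwards. In each group of 6 pigs, 148 measures were searched for a pig whose gap to its nearest neighbour takes up most of the group's range. This gave 23 such values in 296 group tests, where chance gives about 1 in 20, or 14.8, if the tests are independent and unselected. They are not, since 236 were of named genes, many chosen by small p in these data and from the same lists. Each group also mixes the sexes, and some genes were named for lower values in males. The 14.8 is thus a rough guide, and several values of 1 pig are not separate pieces of evidence. Low feed efficiency pig 2, a male, gave 12 of the 23 and high feed efficiency pig 1, also a male, gave 5.

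In low feed efficiency pig 2, far below the rest of its group, were APOA4 (6.005, next 7.89), TIPARP (7.90, next 8.18), TXNDC5 (7.86, next 8.53), SPINK4 (9.20, next 10.59), FCER1G (6.82, next 7.99), TYROBP (6.75, next 8.25), SFRP1 (5.51, next 6.77) and TNFRSF17 (5.65, next 6.71). CYP2C33 was far above it (5.15, next 3.52). The same pig had the lowest scores of its group for amino acid catabolism (-0.18, next 0.09), macrophages (-0.54, next -0.004) and goblet cells (-0.58, next 0.05). High feed efficiency pig 1 was far below its group in C9 (7.75, next 8.65), PKP2 (5.91, next 7.05) and C5 (4.95, next 6.65), and far above it in MSRB2 (5.502, next 5.01) and the hybridization controls (11.02, next 10.62). Low feed efficiency pig 4 stood out in ESPN (6.76, next 6.17), the B cell score (-2.01, next -0.30) and the poly-A controls (7.47, next 7.65). Single values were ICA1L in low feed efficiency pig 6 (1.73, next 2.87), SLC10A2 in low feed efficiency pig 3 (8.71, next 10.11) and the background probe sets in high feed efficiency pig 3 (2.43, next 2.59). In 4 lists the feed efficiency difference differed between males and females by camera: oxidative phosphorylation (-0.38), cytosolic ribosomal proteins (-0.31), brush border (-0.74) and plasma cells (-0.33), each lost with an estimated correlation (adjusted p = 0.945).

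Of the 15 lists lower in high feed efficiency, 8 of absorption, metabolism and cell junctions and 2 of interferon response were weighed, and the rest were not. For the 8 lists, 29.3% of the mean score difference was left without high feed efficiency pig 1 (-0.22 to -0.06), and 75.5% to 166.8% without any other pig, so that array may account for most of it. For the 2 interferon lists 113.5% was left (-0.25 to -0.28), so that array does not account for them, though 58.1% to 147% was left without other pigs. Feed efficiency itself was not decided by the pigs, with exact permutation p of 0.315 and 0.205. As many probe sets at an unadjusted p under 0.05 as the real 1059 came from 64 of 100 splits within sex (highest other 5090) and as many lists as the real 18 from 19 of 100 (highest other 23), so chance cannot be excluded for either. Why a split could reach several times the real count of probe sets was not tested.

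Sex differences were weighed against chance, the arrays of 2 males and the identifier range. Of 100 splits within group, 1, the real one, reached 6332 probe sets at an unadjusted p under 0.05 (highest other 5911). Again the real split alone reached 11 past the threshold (highest other 1). Chance is thus unlikely for both, though 100 splits can give no share below 1 in 100. As many as 11 lists came from 58 of 100 (highest other 26), so chance cannot be excluded for the lists. Without high feed efficiency pig 1 and low feed efficiency pig 2, 5 of 100 splits of the 10 pigs were as large as the real 3582 (highest other 5914), and in identifier range 301 to 310 alone 2 of 16 splits were as large as the real 5102 (highest other 5557), which leaves both the arrays and the range possible in part. For the difference between the sexes, 79 of 100 splits reached 922 probe sets (highest other 6002) and 95 of 100 reached 4 lists (highest other 24), so chance cannot be excluded.

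KDM6A was higher in males on a probe set with a difference of 3.09. Whether the gene as a whole is higher in males is left open, since of its 4 probe sets 2 were higher (3.09 and 1.12) and 2 lower (-0.53, the brightest, and -1.45). The identifier range does not account for it, since the difference within range 301 to 310 was 3.21, with the lowest male at 6.37 and the highest female at 3.74. No biological explanation beyond the sex label was tested, and the probe sequences that could tell a related gene apart were not analysed here.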

How the results depend on the processing

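Leaving out 2 arrays together and testing 1 probe set per gene were chosen only after the results were seen. The direction of a called list turned in no setting that still called it. That of the B cell list by feed efficiency turned without low_FE replicate 4 (adjusted p = 0.341). Named genes were followed under part of the settings only. These were no filter, quantile normalization, trend and robust, array weights and the identifier range or B cell score as a term. Single pigs left out and the mean over a gene's probe sets were the others. Among these values the sign turned in 9 for feed efficiency (1169 kept), 16 for sex (908 kept) and 4 for the difference between the sexes (471 kept). No filter and trend and robust leave a probe set's difference unchanged, so their signs were kept by construction. For feed efficiency no setting called a gene except females alone, with 1 (CYP4A24). For sex, the count of 11 probe sets became 7 with no filter, 4 with the lowest 50% left out and 7 with trend and robust. It became 6 with the identifier range as a term and 4 in range 301 to 310 alone, each time with 3 of the 11 among them. It was 4 without high_FE 1 and low_FE 2 together, and 0 with 1 probe set per gene. A residual component as a term gave 1761, by construction through a smaller residual spread, and looser thresholds gave 580 at an adjusted p under 0.1 and 4232 under 0.2. In leave-one-out fits the count ran from 5 (without high_FE replicate 4, among others) to 416 (without low_FE replicate 1). For the difference between the sexes, 2 probe sets passed at an adjusted p under 0.2, and leave-one-out counts ran from 0 (without high_FE replicate 1, among others) to 1 (without high_FE replicate 3).

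Of 45 lists, 18 were called by feed efficiency, 0 with an estimated correlation, 3 at a preset correlation of 0.05 and 0 by fry, and leave-one-out counts over the 45 ran from 9 (without high_FE replicate 1, 8 of them among the 18) to 19 (without high_FE replicate 4, 17 of them among the 18). With the B cell score as a term 20 were called, 12 of them among the 18. Of the 18 lists, 2 stayed called without each single pig, those of interferon gamma and of antimicrobial defence. By sex the count of 11 among the 45 became 0 with an estimated correlation, 0 at a preset correlation of 0.05, 0 by fry, 6 with quantile normalization, 5 without high_FE 1 and low_FE 2 together and 21 with the identifier range as a term (9 of the 11), with leave-one-out counts from 7 (without low_FE replicate 2) to 20 (without high_FE replicate 3). For the difference between the sexes the count of 4 among the 45 became 0 with an estimated correlation, 2 at a preset correlation of 0.05, 0 by fry, 11 without high_FE 1 and low_FE 2 together (3 of the 4), 7 with the B cell score as a term and 2 with the identifier range as a term, with leave-one-out counts from 3 (without high_FE replicate 5) to 10 (without high_FE replicate 3). On principal components, 1 test passed without high_FE replicate 1 and 0 without high_FE replicate 2 and each other pig. Where no construction is named, the cause was not tested. No paired analysis was possible because each pig has its own identifier and no label links a high pig to a low pig. Signals near the background medians of 2.43 to 2.71 limit what dim probe sets such as RAB11FIP5 can show.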

Other observations

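The relations between scores reported here were chosen only after the result was seen. Over the 12 pigs B cell and germinal centre genes had the largest standard deviation of the 45 list scores, 0.809, ahead of brush border genes at 0.664, but this rank rests on low feed efficiency pig 4, without which they stood at 0.526 and 0.665. Over the 12 pigs the B cell score rose with the cell cycle score (Pearson r = 0.912, permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted over 6 relations 6e-05), and without the 2 pigs farthest out, low feed efficiency pig 4 and high feed efficiency pig 3, r was 0.907. With brush border genes r was -0.598 (permutation p = 0.0654) and the rank correlation -0.881 (permutation p = 0.00035). With T cells r was -0.058 (permutation p = 0.864) and with smooth muscle -0.642 (permutation p = 0.0203, adjusted 0.0609). Without the same 2 pigs these were -0.553 for brush border genes, -0.176 for T cells and -0.351 for smooth muscle. A hypothesis for this is that the pieces of mucosa held differing shares of lymphoid follicle, whose germinal centres divide fast, and an r of 0.912 is consistent with it without proving it, since no histology was analysed here.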
